A study of Mus musculus with 9 samples.

How the data were processed

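RNA from the dorsal telencephalon of 9 mouse embryos at embryonic day 13.5 (5 Dicer knockouts and 4 controls) was measured on 1-colour Affymetrix arrays. Per the labels, total RNA was extracted with a spin-column kit and labelled with biotin by the manufacturer's standard protocol. The only deposited table analysed here holds log2 values that the authors had already processed, with 1 value per gene and array. Per the submitters' processing notes, the affy package was used. Its version, the background correction, the normalization, the summarization and any filter on dim genes are not given in the sources used here. The array type and the probe grouping are not given either. Each of the 12188 entries is listed by an Ensembl mouse gene identifier with a suffix, removed here, and no identifier occurs more than once, so the authors' values are already summarized per gene. The scale was read from the values, which run from 2.72 to 14.1 with similar quartiles on every array. Array medians lie between 7.61 and 7.75. Background signal in array summaries tends to shrink the changes of dim genes toward 0. No background or detection call per gene came with them. No column lacked a sample (0 columns).

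Symbols were to be taken from a table of 49997 RefSeq genes on GRCm38.p6. Its Ensembl column is empty (0 genes filled), so 0 of the 12188 identifiers matched. The files do not pair the identifiers with names, and names were not inferred from identifiers. This ended 3 planned analyses: the level of Dicer1, the tests of 28 fixed gene lists (566 entries) and the test of microRNA seed sites for 22 families, for which no 3' UTR sequence was used here. Sex-linked genes could not be left out of the naming rule for the same reason.

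The main comparison was a limma fit (version 3.58.1 in R 4.3.3; lmFit and eBayes) of knockout against control over all 9 arrays, with no covariate and all 12188 genes tested. A gene was called at a Benjamini-Hochberg adjusted p under 0.05, two-sided. A second limma fit took 3 groups (knockout males, control males, control females, as labelled) with 1 shared estimate of the spread, and gave the contrasts of knockout with control males and of control males with control females. Named genes are those with the largest changes among called genes whose knockout and control values do not overlap. The rule took 12 in each direction, of which 2 in each direction are printed by identifier because no symbols were paired. The design, the naming rule and the alternatives were fixed before the data were examined, except where stated. Groups, replicate numbers and sexes come from the labels. Replicate numbers are not shared between the groups and litters are not assigned to embryos in the sources used here, so no pairing was fitted.

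The fit was tested on simulated data with the real gene means and residual spreads of the knockout against control comparison, in 12188 genes. Of 100 genes changed by 0.5 log2 units 62 were recovered, and of 100 changed by 1 log2 unit 86, with 10 false calls and no wrong sign. With no gene changed it called 0. For the contrast of 2 control males with 2 control females, simulated in 12188 genes, 78 of 100 genes changed by 1 log2 unit and 94 of 100 changed by 2 log2 units were recovered, with 9 false calls. The simulated noise was independent between genes and had the same spread on every array. In the real data the 2 control males differed by 0.415 log2 units (root mean square over genes) and the 2 control females by 0.153. Recovery in the real contrasts may therefore be lower than simulated.

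Alternatives were sex as a covariate, males only, quantile normalization or median subtraction of the deposited values, the dimmest 50% of the genes left out, an intensity trend with robust spread, array weights, Welch statistics, an added minimum change of 0.5 log2 units and each array left out in turn. Choices for several probes per gene and for linear values did not apply. A genotype score places each array on the knockout against control contrast estimated from the other 8 arrays, with knockouts expected near 1 and controls near -1. For cell-cycle phases, gene identifiers were taken from the mouse marker-pair table that ships with the scran package (version 1.30.0), of which nothing else was used. A gene was assigned to a phase where it occurs in at least 10 pairs of that phase and the share of pairs in which it is the higher gene exceeds the share in which it is the lower by at least 0.8. Sets were tested with camera at the preset correlation of 0.01 and at an estimated correlation. The share of called genes in a set was set against 10000 sets of other genes drawn from the same of 20 bins of mean level. Figures were drawn with matplotlib 3.10.9.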

Results

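Gene expression was measured in the dorsal telencephalon, the part of the embryonic forebrain wall that gives rise to the cerebral cortex, of mouse embryos at E13.5 (days of embryonic development). The embryos were either conditional knockouts of Dicer, the ribonuclease that cuts microRNA precursors into mature microRNAs, or controls. The labels give the genotype of the latter only as control, while their sample titles begin with HTZ, which may stand for heterozygous. The controls are therefore not taken to be wild type. The labels describe the knockout samples as depleted of microRNAs. One array was hybridised per embryo, which gave 5 knockout arrays (replicates 5, 7, 9, 10 and 11) and 4 control arrays (replicates 1 to 4). All 5 knockout embryos were labelled male, whereas 2 control embryos were labelled female (controls 1 and 2) and 2 male (controls 3 and 4). The deposited table held log2 values for 12188 genes, each listed by an Ensembl mouse gene identifier. The array medians lay between 7.61 (knockout 5) and 7.75 (control 4), and values ran from 2.72 to 14.1 on the log2 scale. Arrays give no read depth, so the number of embryos limits the precision, and the median standard error of a knockout against control difference was 0.0938 on the log2 scale. The design text describes the embryos as partly littermates. Which ones shared a litter is not in the sources used here, so the tests treat the 9 embryos as independent.

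The table names genes by identifier only, and no symbol could be paired with any of them here. The level of Dicer itself and the gene lists for cortical cell types and microRNA targets are therefore not reported, and genes are described by number, size of change and level. The largest changes among genes whose groups do not overlap are given by identifier.

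The arrays separated by genotype along the first principal component, which carried 44.7% of the variance. The 5 knockout arrays had scores from 4.58 to 23.8 on it and the 4 control arrays from -27.2 to -13.2. The second component carried 24.2% and set control 4, at 28.2, apart from controls 1 to 3, which lay between -15.2 and -12.3. The root mean square difference between arrays was 0.196 to 0.346 log2 units over the 10 pairs of knockouts. It was 0.153 to 0.210 over the 3 pairs among controls 1 to 3 and 0.399 to 0.421 over the 3 pairs that include control 4. Over the 20 pairs of a knockout with a control it was 0.290 to 0.556. No pair of arrays held identical values throughout, and the closest pair, controls 1 and 2, had Pearson's r of 0.99716 across genes.

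**Figure D1:**
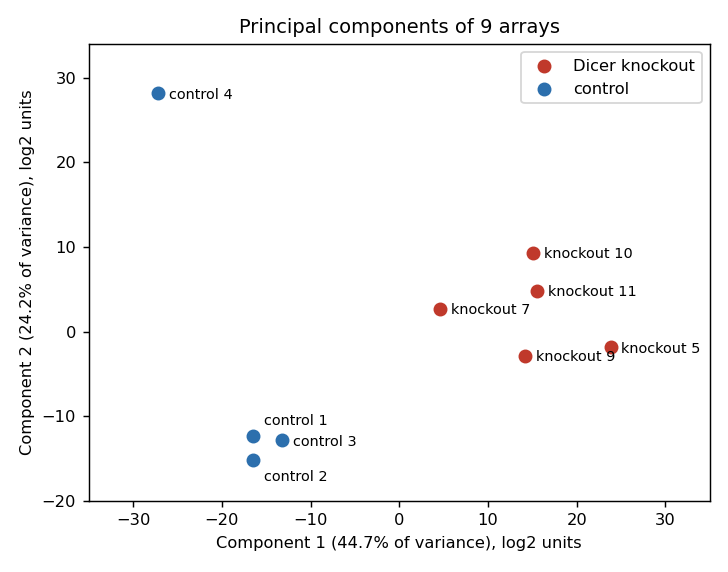
Scores of the 9 arrays on the first and second principal components of the log2 values of 12188 genes, 1 point per embryo, coloured by group. Knockouts lie at 4.58 or above on the first component and controls at -13.2 or below, and control 4 lies at 28.2 on the second component.

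The first comparison asked how the transcriptome of the dorsal telencephalon differs between Dicer knockout and control embryos. Of the 12188 genes, 2997 (24.6%) differed between 5 knockout and 4 control arrays at an adjusted p under 0.05 (limma, two-sided, Benjamini-Hochberg). Of these, 1341 genes were higher and 1656 lower in the knockout. The split depended on the scaling of the arrays, with 1561 higher and 1545 lower after quantile normalization and 1498 and 1500 after subtraction of the array medians. Most changes were small: the median size was 0.43 log2 units among the higher genes (quartiles 0.32 and 0.58) and 0.41 among the lower genes (quartiles 0.32 and 0.53). Changes of at least 1.5-fold were found for 319 of the higher and 276 of the lower genes. At 2-fold the split was uneven in the deposited values, with 61 genes higher and 17 lower, and it was not counted under the other scalings. These counts include genes, described below, at which control 4 lies with the knockouts. For 2510 of the 2997 genes every knockout value lay on one side of every control value. Over all genes regardless of p, 2943 (24.1%) showed such a separation, against 1.59% expected by chance for 5 values against 4. The number of called genes fell to 1976 and that of higher genes to 874 without control 1, and the number of higher genes to 892 without control 2.

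The largest rise among genes with separated groups was that of ENSMUSG00000029546, with 7.85 ± 0.26 (SD, n = 5) log2 units in the knockout against 5.78 ± 0.17 (SD, n = 4) in the controls. This is a log2 change of 2.07 (SE 0.14), or 4.2-fold, with a limma adjusted p of 0.000154. ENSMUSG00000075324 was 3.77-fold higher, at 7.57 ± 0.54 (SD, n = 5) against 5.65 ± 0.29 (SD, n = 4), with a log2 change of 1.91 (SE 0.26) and a limma adjusted p of 0.0016. The largest fall among genes with separated groups was that of ENSMUSG00000048360, from 9.22 ± 0.45 (SD, n = 4) in the controls to 7.63 ± 0.45 (SD, n = 5), a log2 change of -1.59 (SE 0.26) with a limma adjusted p of 0.0029. ENSMUSG00000026227 had a log2 change of -1.49 (SE 0.26) with a limma adjusted p of 0.00373, and means of 6.30 ± 0.26 (SD, n = 5) in the knockout and 7.78 ± 0.64 (SD, n = 4) in the controls. Its value in control 4 was 6.83, between those of the other controls (8.02 to 8.19) and those of the knockouts (5.97 to 6.53). It is also one of 7 genes, described below, that divide controls 1 to 3 from the other 6 arrays by at least 1 log2 unit. The 12 largest such rises ranged from 2.58-fold to 4.2-fold, and the 12 largest falls from 2.02-fold to 3.01-fold. Of those 7 genes, 1 is among these rises and 1 among these falls. Another 3 of the 7 have groups that overlap because control 4 has the level of the knockouts. Their changes were larger than that of any gene with separated groups. The log2 changes were 2.38 and 3.91 for 2 higher genes and -3.49 for 1 lower gene. At all 7 genes control 4 lay on the side of the knockouts, so these changes do not follow genotype alone. Whether they follow sex or litter stays open, as described below.

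**Figure D2:**
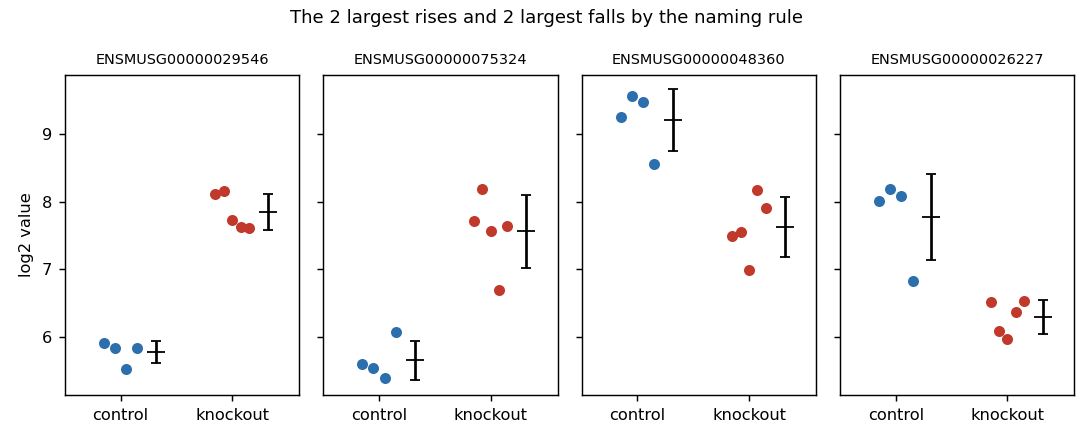
The log2 value of 4 genes on each array, with controls in blue (4 embryos) and knockouts in red (5 embryos). Bars give the mean and SD, and the 2 genes on the left are higher and the 2 on the right lower in every knockout than in any control.

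The share of called genes was higher at higher levels. The genes were divided by mean value into 4 bins of 3047. From the lowest to the highest bin the median standard error fell from 0.1025 to 0.0851 log2 units. Background signal may also shrink the changes of dim genes, so a trend in this share need not reflect the knockout. In the bin with the lowest values, up to 6.12 log2 units, 5.64% were called. The share was 23.5% in the next bin, 31.9% in the one above it and 37.3% in the bin with the highest values, which begins at 8.93. In this top bin 691 of the called genes were lower and 446 higher, so that 60.8% of its calls were lower. In the other 3 bins lower genes made up 49.7% to 53.6% of the calls. The excess of lower genes in the top bin had an odds ratio of 1.44 (Fisher's exact test across genes, two-sided, p = 2.19e-06), where genes are not independent replicates. It depended on the scaling. After subtraction of the array medians the bin had 644 lower and 507 higher genes (odds ratio 1.47, Fisher's exact test across genes, p = 3.23e-07), but after quantile normalization it had 597 and 583 (odds ratio 1.06, p = 0.46 in the same test).

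**Figure D3:**
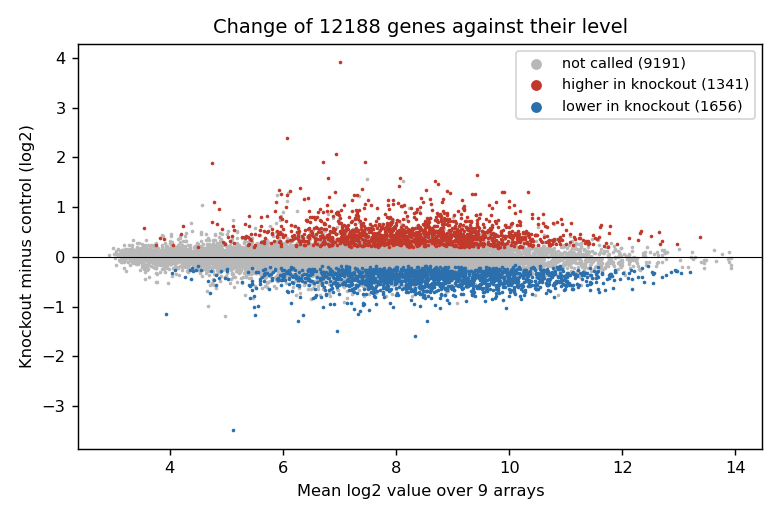
Knockout minus control difference (log2) of 12188 genes against the mean log2 value over the 9 arrays. Points in red (1341 genes) are higher and points in blue (1656 genes) lower in the knockout at an adjusted p under 0.05.

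Because every knockout embryo was labelled male, the genotype comparison was repeated against the controls labelled male, in a fit of 3 groups (5 knockout males, 2 control males and 2 control females). In this contrast 1285 genes passed an adjusted p under 0.05 (limma), 588 higher and 697 lower in the knockout. Of these, 1194 were among the 2997 genes of the comparison with all 4 controls, each with the same sign. All 2997 genes had the same sign in both contrasts, and the change against male controls had a median of 0.925 times the change against all controls. The contrasts share all 5 knockouts and 2 of the 4 controls and the genes were selected by the comparison with all controls, so like signs and similar sizes are largely expected. The median standard error was 1.22 times that of the comparison with all controls. The 4 genes named above kept their calls, with log2 changes of 2.16 for ENSMUSG00000029546, 1.83 for ENSMUSG00000075324, -1.40 for ENSMUSG00000048360 and -1.16 for ENSMUSG00000026227. Their limma adjusted p values were 0.00259, 0.0203, 0.0328 and 0.0397 in that order. A fit of the 7 males alone called 324 genes, of which 196 were higher and 128 lower, so the direction of the split turned. In that fit ENSMUSG00000048360 and ENSMUSG00000026227 lost their calls (limma adjusted p = 0.0613 and 0.0698). The count of the 3-group contrast depended on single arrays. With control 3 counted as female or left out, control 4 would be the lone control male, and without control 4 control 3 would be. Such fits rest on 1 control array, so their counts cannot show what the label of control 3 changes. They are listed only in the part on processing below. Without knockouts 10, 9 and 11 the count was 425, 496 and 253. Leaving out control 1 or control 2 gave the same result as the fit of the 7 males alone, because the 1 control female left adds nothing to the spread.

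The labels also allow control embryos labelled male and female to be compared, 2 against 2. No gene passed an adjusted p under 0.05 in the 3-group limma fit, where the smallest adjusted p was 0.676, and 869 genes had an unadjusted p under 0.05. A fit with an intensity trend and robust spread also called 0 genes. Without knockout 10 the count was 2, and without any other knockout it was 0. With control 3 counted as female or left out, control 4 would be the lone control male. That array stood apart from the other controls, so such a fit cannot show whether the result depends on the label of control 3. Its counts are listed only in the part on processing below. Those of fits with 1 control female left are not listed singly. The widest gap that any gene left between both labelled females and all 7 labelled males was 0.54 log2 units. Other divisions of the arrays were far wider, with gaps of at least 1.5 log2 units at 6 genes. At 4 of them, controls 1, 2 and 3 were separated from control 4 and the 5 knockouts by gaps of 1.90 to 4.66 log2 units. Of these, 3 genes were higher and 1 gene was lower in control 4 and the knockouts. Control 3, which is labelled male, had the level of the labelled females at all 4 genes. At another gene, with a gap of 2.89, controls 3 and 4 and knockout 10 (4.13 to 4.69) lay under controls 1 and 2 and the other knockouts (7.58 to 9.19), so that control 3 was apart from the labelled females. The remaining gene, ENSMUSG00000029546, divided the genotypes. All 4 genes that set controls 1 to 3 apart were among the 2997 genes called between genotypes, although control 4 had the level of the knockouts. Without the 7 genes that divided the arrays in this way by at least 1 log2 unit, the genotype comparison called 2990 genes, a fit chosen after the data were seen.

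**Figure D4:**
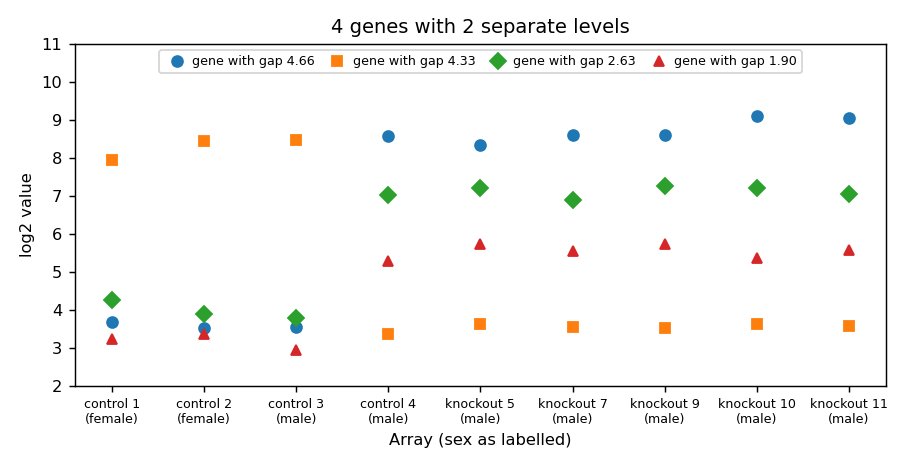
The log2 values of 4 genes on the 9 arrays, with the labelled sex under each array. At each gene controls 1, 2 and 3 lie at one level and control 4 and the 5 knockouts at another, with the gap between the levels (1.90 to 4.66 log2 units) in the key.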

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

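The tests on control 3, control 4 and knockout 7 in this part were chosen after the results were seen, and the splits of the arrays were planned before. ENSMUSG00000026227 was flagged because control 4 stood apart from its group: its value was 6.835 log2 units against 8.016 to 8.19 in controls 1 to 3, a gap of 0.872 of the group's range where 0.829 is the 95% limit for 4 samples. It was the only one of 14 tests (7 measures in 2 groups) to pass, and chance flags about 1 in 20 groups. The same test on the distance of control 4 from the other controls gave 0.823.

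The first pattern is the set of 4 genes at which controls 1 to 3 differ from control 4 and all knockouts by at least 1.5 log2 units, in either direction. No gene divided the labelled females from the labelled males by that much (0 genes). A wrong sex label of control 3 stays open: the 4 genes raised the question and so cannot test it, and no sex-linked gene could be identified. With the labels as given, the widest gap between the sexes at any gene was 0.54 log2 units. With control 3 taken as female, the 4 genes would divide the sexes by 1.90 to 4.66 log2 units. At another gene with a gap of 2.89, control 3 lay with control 4 and knockout 10, apart from the labelled females. An on/off level need not follow sex, so that gene does not bear on the label. Control 4 being an unrecognised knockout is argued against by its genotype score of -0.467, on the control side and close to the -0.53 of control 3. A difference in litter or background shared by controls 1 to 3 stays open too and was not tested. If the label is wrong, control 4 is the only male control, and sex and genotype are told apart by that 1 array.

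The second pattern is the distance of control 4 from the other controls, with a root mean square deviation of 0.397 log2 units against at most 0.216 for controls 1 to 3, and 448 genes off by at least 1 log2 unit where no other array had over 64. An intensity-dependent trend left by the normalization could explain only 0.403% of the variance of its deviation across genes. A few genes with very large deviations do not account for it either, since 0.352 remained after the 121 most deviating genes were removed. Embryo sex alone is argued against. By its label control 3 is male like control 4, and if that label is wrong, sex would bring control 4 nearer to the knockouts, all labelled male. Instead 5 of 5 knockouts lay farther from control 4 than from each of controls 1 to 3. Tissue composition, stage and hybridisation quality stay open, as no value here decides between them.

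The third pattern is the position of knockout 7 nearer to the controls, with a genotype score of 0.263 where the other knockouts had 0.804 to 1.22. Over the 2907 genes called without it, knockout 7 kept a median share of 0.645 of the knockout shift. Its 95% bootstrap interval over genes, 0.638 to 0.658, leaves out their correlation and the spread between embryos. The other knockouts kept 0.854 to 1.19, each over the genes called without it. A share of 0.645 argues against knockout 7 being a control embryo. A smooth trend on level is argued against as well, since removing it left the score at 0.261, under the 0.833 of the next knockout. Admixture of control tissue would give like shares in both directions. On the linear scale the share was 0.58 for higher and 0.711 for lower genes, a difference of -0.131 (interval over genes -0.152 to -0.105). The difference is too small to exclude admixture. Its interval leaves out 0, but also leaves out the spread between embryos. An admixture and a biologically weaker effect of the knockout in this embryo therefore cannot be told apart.

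Of 100 drawn splits of the 9 arrays out of 126, only 1, the real one, gave as many as 2997 genes. This is the smallest share that such a draw can give. Splits that mix the genotypes count the genotype difference as spread, so few calls are expected there. Embryos that share a litter or a sex are not interchangeable, so the splits cannot tell an effect of genotype from these. The highest other split gave 1862 genes. It set knockouts 5, 9, 10 and 11 against knockout 7 and the 4 controls, and so differs from the real one in the place of knockout 7 alone. No gene was called in 95 of the 99 others.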

How the results depend on the processing

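Every alternative fit of knockout against control kept the sign of all 2997 called genes that it tested, but this was largely fixed in advance. All alternatives share arrays with the main fit. Those that change only the spread or the genes tested use the same differences of means. For the 2510 called genes whose groups do not overlap, leaving out arrays cannot reverse a sign. The number called moved by over 1.5 times in some. It was 1285 (588 higher, 697 lower, 1194 shared) with sex as a covariate, the same fit as the 3-group contrast because every knockout is labelled male. It was 324 (196 and 128) with males only, 4562 (2136 higher) with array weights and 1973 (834 higher) with Welch statistics. With a minimum change of 0.5 log2 units it was 982 (481 and 501). The causes were not tested. Leaving out each array gave 1976 (without control 1) to 3263 (without control 4) genes, 874 to 1484 higher and 1102 to 1779 lower. Without control 4 and knockout 7 together, an alternative chosen after seeing the data, it was 3326 (1525 higher, 1801 lower). Quantile normalization (3106), median subtraction (2998), the dimmest 50% left out (2465) and a trended robust spread (3021) stayed within 1.5 times. With males only, ENSMUSG00000048360 and ENSMUSG00000026227 lost their calls (adjusted p = 0.0613 and 0.0698), and with Welch statistics ENSMUSG00000026227 did (0.0666). Leaving out each array gave 76 to 2297 genes for knockout against control males and 0 to 977 for male against female controls. With control 3 counted as female, also chosen after seeing the data, these were 2545 and 1326, with control 4 as the lone male control, assumed to vary like the other groups. Both ends of the range for knockout against control males come from fits with control 4 or control 3 left out. The upper end for male against female controls comes from the fit without control 3. Each of these fits leaves 1 control male, so no conclusion is drawn from the counts of such fits. No analysis paired by litter was possible, because which embryos shared a litter is not in the sources used here. No background signal per gene was used, so a floor for dim genes is unknown.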

Other observations

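The cell-cycle test was chosen after the table was seen to hold no names, and its prediction was written before its result was seen. Genes that mark phases of the cell cycle in mouse cells did not pass a test for a shift as sets between knockout and control embryos. Of 128 measured genes that mark G1, 29 rose and 26 fell in the knockout (33 and 28 adjusted over the list alone), with a median log2 change of 0.04 (95% bootstrap interval over genes, which leaves out their correlation, -0.01 to 0.12). Of 108 genes that mark S phase, 18 rose and 12 fell (18 and 12 adjusted over the list alone), with a median of 0.04 (-0.01 to 0.08). Of 103 genes that mark G2 and mitosis, 14 rose and 15 fell (14 and 15 adjusted over the list alone), with a median of 0.01 (-0.07 to 0.05). The hypothesis that each set differs as a whole was tested with camera. With an estimated correlation the adjusted p over the 3 sets was 0.725 for G1, 0.725 for S and 0.845 for G2/M, and with the preset correlation it was 0.24, 0.24 and 0.604. The intervals of the S and G2/M medians lie within 0.1 log2 units of 0, while that of G1 reaches beyond. Leaving out each array gave adjusted p values of 0.389 to 0.96 with an estimated correlation, and medians of 0.0329 to 0.0716 for G1, 0.0285 to 0.0598 for S and -0.0282 to 0.0236 for G2/M. Against the controls labelled male the medians were 0.0133, 0.0185 and -0.0472 in that order. Members nevertheless changed in both directions, with fry's mixed p at 5.32e-07, 1.29e-07 and 7.97e-08 for the 3 sets. That test does not compare a set with other genes, and 24.6% of all genes were called. Small p values are therefore likely for other sets too and do not single out these 3. The share called was 43% for G1 (55 of 128), 27.8% for S and 28.2% for G2/M, against 30.7%, 32.4% and 31.3% on average in sets of other genes drawn at the same levels. These draws were added after the shares were seen, so they describe the share of G1 and do not test it.

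Some genes varied widely among the knockout embryos. At 25 genes the 5 knockouts spanned at least 2 log2 units, up to 3.82. A group of 7 of them, chosen because they followed the gene of widest range across the knockouts with a correlation above 0.9, had mean log2 values of 8.45 in knockout 5, 7.60 in knockout 9, 6.91 in knockout 10, 6.28 in knockout 11 and 5.51 in knockout 7. In controls 1 to 4 the same genes had means of 6.51, 6.32, 5.52 and 4.70.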
